A study of Folsomia candida with 21 samples.

How the data were processed

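Springtails (Folsomia candida, a soil-living hexapod used in soil toxicity testing) were held in jars of soil and their RNA was read on 21 one-colour Agilent arrays, 1 jar per array. Per the labels, each jar held about 30 animals 23 days old, kept for 2 days in about 30 g of soil at 50% of its water-holding capacity and 20 °C, and 500 ng of the pooled RNA of a jar was labelled with Cy3. The sample titles give 6 field soils described as polluted, L1 to L6, and LUFA, a standard natural soil, with 3 jars each.

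The deposited scanner files hold 153910 spots per array, of which 4854 are controls and 149056 carry 74528 probes of 60 bases, each spotted 2 times. Their intensity columns were made by the authors with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes, and the processed signal in them is a background-corrected intensity on a linear scale, not yet scaled between arrays. The notes also name limma, with no version. The series' deposited value table holds log2 values of the same spots. Its median was 8.13 on every array and its ranks followed the mean signal (Spearman 0.999 to 1.000 across spots), so it appears scaled to 1 distribution without background subtraction. How it was scaled is not given in the sources used here, so it served as an alternative only. Flag columns in the deposited files (other than intensities) mark outlier spots and spots well above background.

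The main values were log2 of the processed signal minus the array's 75th percentile over non-control spots. The 2 spots of a probe were averaged, an outlier spot (2 to 85 per array) being replaced by its partner. A probe counted as well above background on an array when both spots did, and the 67168 probes (90.1%) that did so on at least 3 of the 21 arrays were tested. The array's description column reads unknown for every probe and none of the 74528 identifiers matched the reference gene table of assembly ASM221717v1, so no probe could be given a gene name by its identifier. The probe sequences were not aligned to a genome, so no probe was given a place in it. The 30 gene lists and the rule for named genes, both built on annotation text, therefore matched nothing. Probes are reported by the array's identifier and sequence, and those singled out in the text were chosen after their values were seen. The 74528 probes hold 67023 different sequences, 7505 of them carried by 2 identifiers. Of the tested identical pairs, values correlated at 0.996 to 0.999 per array across 7214 pairs, and the 2 spots of a probe at 0.988 to 0.996.

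One linear model with a mean per soil was fitted to all 21 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates, with 14 residual degrees of freedom. Contrasts were each field soil against LUFA, the mean of the 6 field soils against LUFA, and the 15 pairs of field soils, with moderated F tests over the 7 soils and over the 6 field soils. P-values were two-sided and adjusted by Benjamini-Hochberg over the 67168 probes within each contrast, with a threshold of 0.05. Each jar is a separate exposure per the labels, so the spread between jars is the error of every test. The number of arrays limits the precision. Where a probe was not well above background on all arrays of a soil, the difference is given as a bound: the brighter soil's mean against the mean, per array, of the higher of the dim probe's own signal and the lowest signal among probes well above background. Bounds within a slide, per spot and in other settings use the floor of that array, spot level or setting. An adjusted p given beside a bound belongs to the difference of the measured signals, and the bounds themselves were not tested. Single-value permutation tests used 10000 to 100000 random relabellings.

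The arrays lay on 7 slides, numbered 1 to 7 in the text, with 2 to 4 arrays each, all scanned on 1 day with 1 scan per slide. LUFA arrays were on 3 slides, together with L1, L2, L3, L5 and L6 arrays but never with an L4 array. Slide was entered as a fixed and as a random block, and differences within slides were computed.

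Alternatives chosen before the data were examined, apart from the exceptions below, were normexp background correction (offset 50), quantile normalization, the deposited log2 value table, no filter, a filter on probes well above background on all 21 arrays (56493), both slide blocks, the replicate number as a block, eBayes with trend and robust variance, array weights, only the 6 arrays of 2 soils, a 2-group fit, and leaving out each jar. One value per distinct sequence, the removal of 2795 probes with a stretch of sequencing adapter or cDNA primer, adjustment over all 15 pairs together, both slide blocks, trend and robust variance, array weights and leaving out jars for the field soil pairs, and the alternatives of the L1 and L4 comparison were chosen after seeing the data. Testing each probe by itself is the same as the main setting, since each identifier has 1 probe, and the gene list alternatives had no members to run on.

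The fit was tested on simulated data with the residual structure of these arrays and 200 changed probes, in 10 runs of 67168 probes. For L1 against LUFA, 22.2% of probes changed 2-fold, 68.0% of those changed 4-fold, 85.8% at 8-fold and 94.0% at 16-fold were called, with 0.7 false calls per run. For the average of the 6 field soils, 39.2%, 80.5%, 93.5% and 97.5% were called at those folds, with 1.8 false calls per run. The Benjamini-Hochberg cutoff is easier to pass with 200 changed probes than where few are called. These shares are therefore too high for the real contrasts, and a missing call does not show that a probe was unchanged. Chance similarity between soils that share the LUFA arrays was simulated 100 times in the same way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.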

Results

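Expression was measured in springtails kept for 2 days in 1 of 7 soils: the standard soil LUFA, or 1 of 6 polluted field soils, L1 to L6, with 3 jars of pooled animals per soil. The series title places the work in soil quality assessment, to which expression profiles were to be added. The 75th percentile of the processed signal lay between 878 and 2054 units across the 21 arrays, and 82.0% to 90.0% of spots per array were well above background. Of 74528 probes, 67168 were tested. No probe carried a gene name and the sequences were not aligned to a genome, so results are given per probe with its 60-base sequence. Neither gene, exon nor chromosome is stated for any of them.

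In the comparison of the 6 field soils on average with LUFA, 2 probes stood far above the rest. Probe a9999999_1 (sequence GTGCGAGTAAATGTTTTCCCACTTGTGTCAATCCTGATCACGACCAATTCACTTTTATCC) was 41.5-fold higher in the field soils, a log2 difference of 5.37 (SE 0.39, adjusted p = 1.24e-05). Probe a347_940 (sequence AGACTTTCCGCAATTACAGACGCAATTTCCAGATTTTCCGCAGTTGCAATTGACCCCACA) was not well above background in any of the 3 LUFA jars and was well above it in all 18 field soil jars. Its rise was at least 5.82-fold, and its measured log2 difference of 4.28 (SE 0.38) had an adjusted p of 0.000136. Every one of the 18 field soil jars lay above all 3 LUFA jars for both probes.

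The level of a9999999_1 in LUFA was -1.0 ± 0.14 (SD, n = 3), in log2 units relative to the array's 75th percentile. It was 3.99 ± 0.29 in L1, 5.36 ± 0.41 in L2, 5.18 ± 0.28 in L3, 3.54 ± 0.94 in L4, 4.11 ± 0.53 in L5 and 4.04 ± 1.29 in L6 (SD, n = 3 each). The measured level of a347_940 was -9.05 ± 0.27 in LUFA and between -5.18 ± 0.33 in L6 and -4.31 ± 0.95 in L3 (SD, n = 3 each). With slide as a fixed block, a9999999_1 was higher by 5.63 (SE 0.40, adjusted p = 0.00261, the highest over its alternatives). The rise of a347_940 was then at least 5.35-fold (SE of the log2 bound 0.47, against 0.40 without the block). Its measured difference with the block, 4.12 (SE 0.46), had an adjusted p of 0.0986. On the 3 slides that held LUFA, the 6 field soil arrays exceeded the LUFA array of their slide by 4.21 to 6.69 for a9999999_1, and for a347_940 by bounds of 1.88 to 3.40. The call of a347_940 was also lost with normexp background correction (at least 1.91-fold, adjusted p = 0.879) and in the value table (at least 2.19-fold, adjusted p = 0.368).

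**Figure D1:**
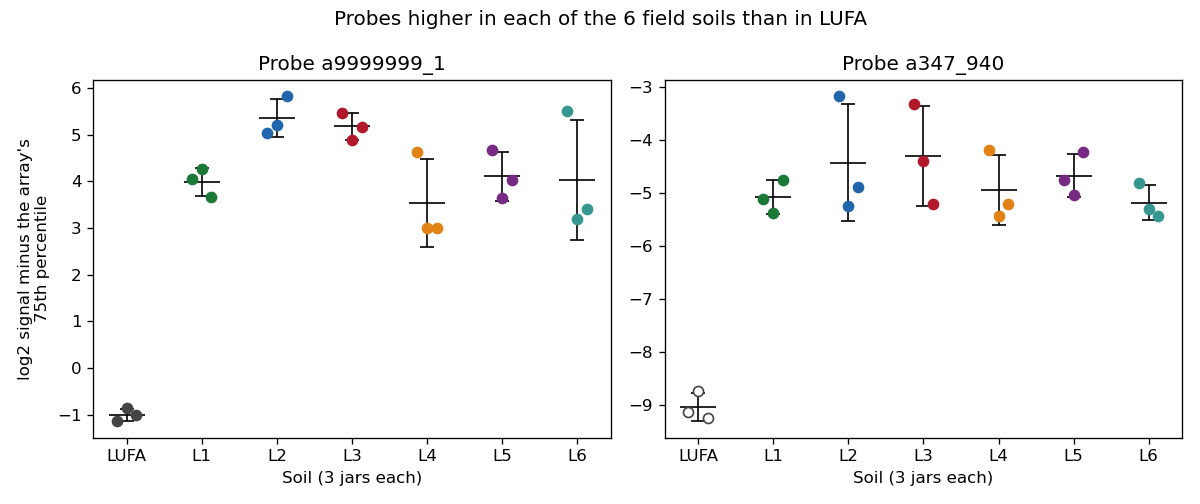
Log2 signal relative to the array's 75th percentile (vertical axis) of probes a9999999_1 and a347_940 in each of the 7 soils (horizontal axis). Points are jars, horizontal bars and whiskers are the mean and SD of 3 jars, and open points were not well above background. For both probes the 3 LUFA jars lie below all 18 field soil jars.

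A further 4 probes passed the threshold in the average contrast, which made 5 that rose and 1 that fell. The 3 further rises were between 0.87 and 1.08 on the log2 scale. Among them, a276456_18 and a222038_19 carry 1 sequence, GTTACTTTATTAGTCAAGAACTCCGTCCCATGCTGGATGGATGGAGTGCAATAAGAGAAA, and rose by 1.02 (SE 0.14, adjusted p = 0.0272) and 1.08 (SE 0.16, adjusted p = 0.0385). The third, a928571_7, rose by 0.87 (SE 0.12, adjusted p = 0.0272). The probe that fell, a27362_412 (sequence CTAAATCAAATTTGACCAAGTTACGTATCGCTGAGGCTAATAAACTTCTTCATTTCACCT), fell by 1.23 (SE 0.18, adjusted p = 0.0327). Its level was -0.62 ± 0.34 in LUFA and between -2.22 ± 0.32 (L3) and -1.13 ± 0.35 (L4) in the field soils (SD, n = 3 each). The second probe with that sequence, a34322_373, had a log2 difference of -1.26 and an adjusted p of 0.0659. With slide as a block 1 probe was called in place of 6, and in the plain 2-group fit of 18 against 3 arrays 2 were called. Leaving out 1 jar gave between 2 and 10 calls, and a27362_412 lost its call in 13 of these 21 fits and in 5 of 13 other settings. The balance of directions also moved: there were 4 rises and 4 falls on probes well above background on all arrays, 3 and 4 in the value table, 2 and 2 with trend and robust variance, 2 and 4 without LUFA replicate 3, and 5 and 5 without L6 replicate 3.

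Each field soil was also set against LUFA by itself, which asks whether the soils can be told from the standard soil one at a time. Probes a9999999_1 and a347_940 rose in each of the 6 comparisons, and 2 further calls were made, 1 in L4 and 1 in L5. The rise of a9999999_1 was 31.9-fold in L1 (adjusted p = 0.00199), 82.4-fold in L2 (adjusted p = 5.7e-05), 72.7-fold in L3 (adjusted p = 8.79e-05), 23.3-fold in L4 (adjusted p = 0.0076), 34.7-fold in L5 (adjusted p = 0.00142) and 32.9-fold in L6 (adjusted p = 0.00175). The rise of a347_940 was at least 4.68-fold in L1 (adjusted p = 0.0178), 7.35-fold in L2 (adjusted p = 0.00222), 8.02-fold in L3 (adjusted p = 0.00151), 5.17-fold in L4 (adjusted p = 0.011), 6.22-fold in L5 (adjusted p = 0.00466) and 4.37-fold in L6 (adjusted p = 0.0248). In 20 simulations of soils that did not differ from the shared LUFA arrays, no probe was called in all 6 comparisons, against the 2 observed. The simulated values were normally distributed, which the real jars need not be, so chance is not excluded by this. Of 100 labellings of the arrays, the real one included, 7 gave at least the real 2 calls in the F test over the 7 soils. That count is of any probes in another test. How often a labelling gave a probe called in all 6 comparisons was not tested.

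Probe a928571_7 (sequence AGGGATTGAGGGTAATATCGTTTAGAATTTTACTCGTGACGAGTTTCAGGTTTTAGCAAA) made the third call in L4. It rose by 1.23 on the log2 scale (SE 0.16, adjusted p = 0.0141), from -5.17 ± 0.08 in LUFA to -3.94 ± 0.24 (SD, n = 3 each). This call was lost in 5 of 6 fits without a jar and in 6 of 13 other settings, where the difference ran from 0.66 to 1.23. Probe a276456_18 made the third call in L5, where it rose by 1.34 (SE 0.18, adjusted p = 0.029), from -4.70 ± 0.10 to -3.35 ± 0.15 (SD, n = 3 each). It lost this call in all 6 fits without a jar and in 5 of 13 other settings, with differences of 0.70 to 1.37 in these settings. No probe fell in any of the 6 comparisons of the main fit. With array weights, 11 of 19 calls in L2, 11 of 21 in L5 and 6 of 8 in L6 were falls, and without LUFA replicate 3 there were 3 falls in L3, 3 in L5, 2 in L6 and 1 in L1. At an unadjusted p under 0.05 there were 884 probes in L1, 2853 in L2, 5083 in L3, 5791 in L4, 3681 in L5 and 1980 in L6, where 3358 of 67168 would pass by chance.

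The calls in single soils depended on the model and on single jars. With slide as a block the counts were 0 in L1, 1 in L2, 4 in L3, 0 in L4, 2 in L5 and 1 in L6, and for a9999999_1 the adjusted p rose to 0.131 in L1 and 0.393 in L4, at log2 differences of 4.92 (SE 0.52) and 4.69 (SE 0.56) against 5.0 and 4.54 (SE 0.52 each) without the block. At the degrees of freedom of the main fit, these t values would give adjusted p of 0.00317 and 0.0161, so the calls ended with the lost degrees of freedom. Probe a347_940 lost its call in all 6 soils with slide as a block (bounds of 3.73-fold to 8.90-fold, lowest adjusted p = 0.102), and also in all 6 with normexp and in the value table. Without 1 jar it lost its call in all 6 fits of L1 and of L6, in 4 of 6 of L4 and in 2 of 6 of L5. No L4 array shared a slide with a LUFA array, and without L4 replicate 1 or any 1 LUFA jar L4 had 0 calls.

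The level of a9999999_1 also varied among the field soils, with the highest means in L2 and L3, but a permutation test over the 6 soils gave p = 0.0601 (0.12 after Benjamini-Hochberg over the 2 probes tested). The same permutation test gave p = 0.58 for a347_940. Over the 18 field soil arrays the levels of both probes had a Pearson correlation of 0.48 (permutation p = 0.0445) and a Spearman correlation of 0.44 (permutation p = 0.0695), the only pair for which a relation was computed. Without the 2 arrays farthest from the median the Pearson correlation was 0.40, and within soils it was 0.29. Slides held at most 4 arrays, too few for a value within each, and a value pooled within slides was not computed.

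In the F test over all 7 soils, a9999999_1 (adjusted p = 0.00119) and a347_940 (adjusted p = 0.0193) were the 2 probes that differed. None was called once slide was a block. No probe passed the limma F test over the 6 field soils, where 2673 had an unadjusted p under 0.05, and the count with slide as a block was also 0. Array weights gave 3552 over the 6 field soils and 1770 over the 7, and leaving out L2 replicate 2 gave 1 over the 6.

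Of the 15 pairs of field soils, the pair L1 and L4 gave 5 called probes and the other 14 pairs gave none. Of the 5, 4 were lower in L4 than in L1, by 3.44 to 4.07 on the log2 scale, each with an adjusted p of 0.0346. Probe a52355_275 (sequence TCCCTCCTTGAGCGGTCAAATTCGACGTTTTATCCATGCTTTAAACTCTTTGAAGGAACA) was at 3.90 ± 1.03 in L1 and -0.17 ± 0.51 in L4 (SD, n = 3 each), a 16.7-fold difference. Probe a81689_51 (sequence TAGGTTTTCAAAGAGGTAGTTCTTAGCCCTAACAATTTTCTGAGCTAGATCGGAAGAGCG) was at 1.67 ± 0.68 in L1 and -2.32 ± 0.89 in L4, and a113900_56 (sequence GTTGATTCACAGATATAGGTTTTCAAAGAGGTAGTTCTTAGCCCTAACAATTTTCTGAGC), which overlaps it by 45 bases, at 1.81 ± 0.79 and -2.20 ± 0.88 (SD, n = 3 each). Probe a1237569_5 (sequence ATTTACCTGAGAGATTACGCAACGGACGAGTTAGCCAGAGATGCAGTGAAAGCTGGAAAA) was at -1.35 ± 0.68 in L1 and -4.78 ± 0.62 in L4 (SD, n = 3 each). In LUFA these 4 probes lay between both soils, at 1.46 for a52355_275, -0.86 for a81689_51, -0.82 for a113900_56 and -3.61 for a1237569_5, and in none of the 4 did L4 or L1 differ from LUFA past the threshold. The 4 were not low in L4 against L1 alone. Their L3 minus L4 differences were 3.45 to 4.17 (adjusted p = 0.0533). L4 minus L5 gave -3.81 to -3.40 (adjusted p = 0.0817) and L4 minus L6 -3.77 to -3.39 (adjusted p = 0.117). L2 minus L4 gave 2.76 to 3.23 (adjusted p of 0.582 to 0.986). Probe a1455008_4 (sequence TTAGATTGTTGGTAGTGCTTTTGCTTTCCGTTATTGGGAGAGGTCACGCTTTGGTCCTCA) was well above background in the 3 L4 jars and in none of the L1 jars, and was at least 2.34-fold higher in L4. Its measured L1 minus L4 difference of -2.75 (SE 0.36) had an adjusted p of 0.0346. This probe was well above background in all 3 LUFA jars too (mean -6.85), and in no jar of L2, L3, L5 or L6.

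On the 2 slides that held both L1 and L4, the 4 probes were higher in L1 by 3.91 to 5.18. Probe a1455008_4 kept its call with slide as a block and the 4 others lost theirs (adjusted p = 0.333), at differences of 3.24 to 4.01 (SE 0.49 to 0.65) against 3.44 to 4.07 (SE 0.49 to 0.58) without it. The call of a1455008_4 was lost in 4 of 11 other settings and in 5 of 6 fits without a jar of either soil, and with normexp its measured difference was -0.06 (SE 0.31, adjusted p = 0.965). Adjustment over all 15 pairs together left 0, and leaving out 1 jar gave between 0 and 51 calls. Which pair held the calls also changed. Array weights gave 0 between L1 and L4, but 18065 between L2 and L6, 2824 between L4 and L6 and 1703 between L2 and L4.

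**Figure D2:**
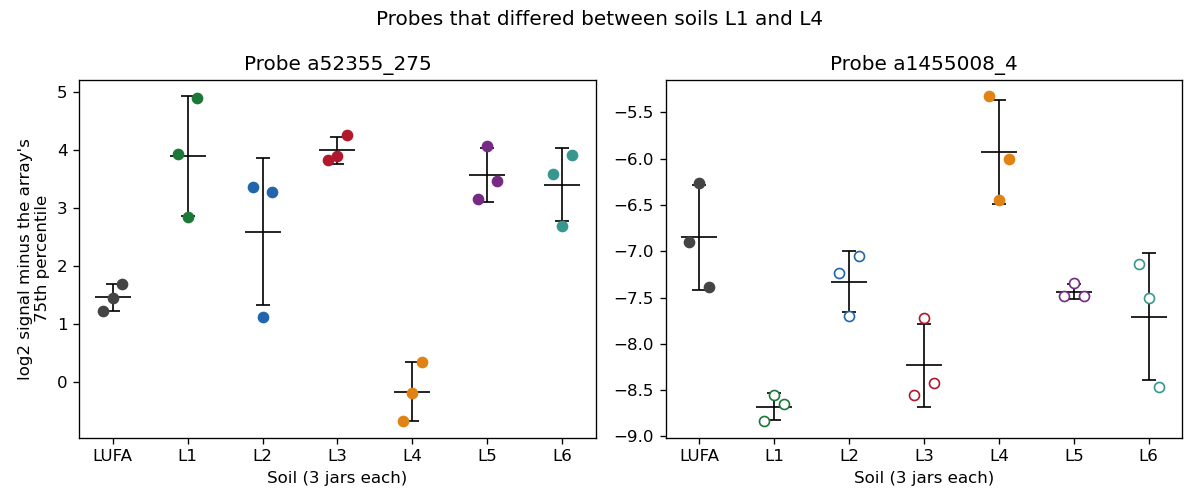
Log2 signal relative to the array's 75th percentile (vertical axis) of a52355_275 and a1455008_4 in each of the 7 soils (horizontal axis). Points are jars, bars and whiskers are the mean and SD of 3 jars, and open points were not well above background. The 3 L4 jars lie below all other jars for a52355_275, between -0.67 and 0.35.

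The log2 differences from LUFA were compared between soils across all 67168 probes, which are not independent replicates. Correlations ran from 0.22 (L3 and L5) to 0.75 (L5 and L6), with a mean of 0.52. Unchanged soils that shared the 3 LUFA arrays gave a mean correlation of 0.48 in simulation, with 90% of the simulations between 0.18 and 0.75. The mean covariance was 0.131 against a simulated 0.116 (0.0262 to 0.272). On the 56493 probes well above background on all arrays it was 0.0750 against a simulated 0.0755, so no excess was left there.

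Over all probes, soil accounted for 31.3% of the variance between arrays, where chance gives 30%, and a permutation test gave p = 0.359. The split of field soils against LUFA accounted for 5.37%, where chance gives 5%, with an exact permutation p = 0.353 over all 1330 possible choices of 3 arrays. Slide accounted for 40.4% (permutation p = 0.0109) and position on the slide for 13.5% (permutation p = 0.638). With Benjamini-Hochberg adjustment over these 4 tests none but slide passed, at 0.0436. Jars of 1 soil correlated with each other at 0.961 on average and jars of different soils at 0.961. Within each of the soils, 1797 (L5) to 4594 (L4) probes differed more than 4-fold between the 3 jars.

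**Figure D3:**
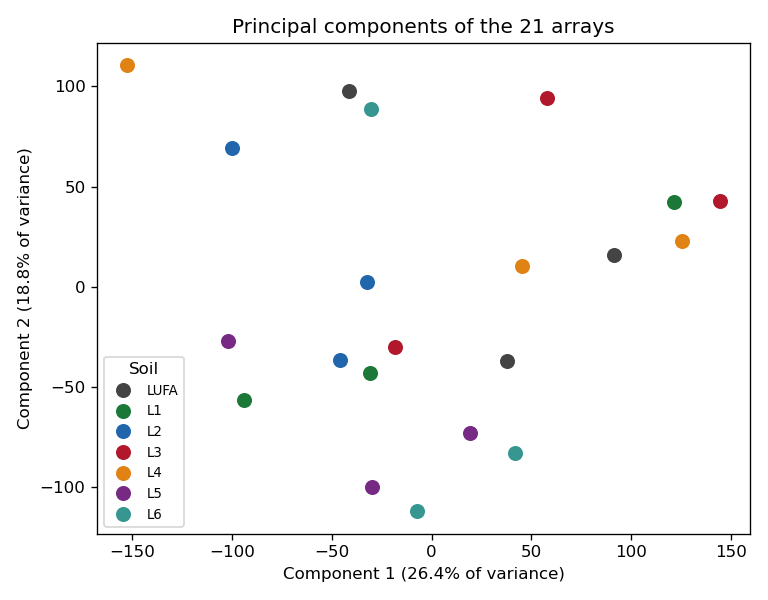
The 21 arrays on principal components 1 (horizontal axis, 26.4% of the variance) and 2 (vertical axis, 18.8%) of the 67168 tested probes. Each point is a jar, coloured by soil. Jars of 1 soil lie apart: soil accounts for 22.3% of the variance of component 1 and 33.9% of component 2.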

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

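All tests on the slide and on single jars in this part were chosen after the results were seen. Splitting the arrays was set beforehand as a kind of test, but the pair L1 and L4 was picked for it after its calls were seen. The soils L1 and L4 differed from each other in 5 probes by the direct contrast: a52355_275 by 4.07, a113900_56 by 4.01, a81689_51 by 3.99 and a1237569_5 by 3.44 on the log2 scale, each higher in L1, and a1455008_4, not well above background in any L1 jar, at least 2.34-fold higher in L4 (bound -1.23 on the log2 scale). Another probe that was low in L4, a234701_12 (sequence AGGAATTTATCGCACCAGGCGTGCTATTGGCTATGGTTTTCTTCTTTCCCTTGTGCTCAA), followed the mean of the first 4 over all 21 arrays with a correlation of 0.96, and its L1 minus L4 difference of 3.77 had an adjusted p of 0.138.

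For the 4 probes low in L4, the smallest difference within slides 1 and 6 was 3.91. The L1 and L4 arrays of these slides were, however, among those on which the probes were picked, so these differences are no separate test of slide. For each of the 4, the lowest L1 jar lay at least 2.22 above the highest L4 jar. The probes were picked for a large difference against their spread in these same jars. Such a gap was therefore favoured by the choice, and it decides nothing about a single stray jar. The call itself depends on single jars, also of other soils: without L1 replicate 1 the pair gave 51 calls, and without any one of the 3 L4 jars, L1 replicate 3, L2 replicate 1, L3 replicate 1 or 3, L5 replicate 2 or 3, or LUFA replicate 1 it gave 0. Within slides, the bound for a1455008_4 was -2.51 on slide 1 and -0.30 on slide 6. Of the 10 splits of the 6 arrays 2 gave as many calls, the real one with 5 and the highest other with 624, and 10 splits are too few to exclude chance. Probes a81689_51 and a113900_56 share 45 bases and the rest of a81689_51 is mostly adapter, so these 2 cannot be counted as separate transcripts. The 4 probes therefore cannot be counted as 4 transcripts, and how many they read was not tested. A difference in the soils themselves stays open. For the 15 pairs of field soils together, the 18 field soil arrays were given 100 labellings, the real one included. Of these, 20 gave at least the real 5 calls and the highest gave 22686, so chance was not excluded for this count.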

How the results depend on the processing

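Adjustment over all 15 pairs, one value per sequence, removal of adapter-bearing probes, every alternative of the L1 and L4 pair, and for the field soil pairs both slide blocks, trend and robust variance, array weights and leaving out jars were chosen after seeing the data, as were the tests of why calls ended with slide as a block. None of the 10 probes followed through the alternatives reversed its difference. Probe a9999999_1 kept its call in 140 of 148 combinations of contrast and alternative, and in the average contrast in all 13 settings and all 21 fits without a jar (log2 5.18 to 5.63, and 5.25 to 5.45). Its 8 lost calls were in L1 and L4 with slide as a block (adjusted p = 0.131 and 0.393), in L4 and L6 with only 6 arrays (0.524 and 0.0636), and in L4 without L4 replicate 1 (0.0504) or without LUFA replicate 1, 2 or 3 (0.0791, 0.0568 and 0.0807). Probe a347_940 kept 100 of 141. In the average contrast its bound went from 5.82-fold to 1.91-fold with normexp and 2.19-fold in the value table, and both lost the call. The bound was 5.35-fold with slide as a block (SE of the log2 bound 0.47 against 0.40) and 8 residual degrees of freedom remained in place of 14. For the measured difference, the main t at the degrees of freedom of the slide fit gave an adjusted p of 0.0128. The t of the slide fit at the main degrees of freedom gave 0.00291, so neither change alone ended the call. For the 4 probes low in L4 these were 0.403 and 0.0594 to 0.0729, so either change alone did. Without 1 jar the call of a347_940 was lost in all 6 fits of L1 and of L6, in 4 of 6 of L4 and in 2 of 6 of L5.

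With normexp, 1 probe was called in each of the 6 soils and in the average, and 3 between L1 and L4. With the value table it was 1 in each soil, 2 between L1 and L4 and 1 over the 7 soils, and the average contrast had 3 rises and 4 falls against 5 and 1. With normexp the median log2 difference of all probes ran from -0.12 to 0.17 over the contrasts. Requiring all 21 arrays above background gave 1 call in L1, L2, L3 and L6, 12 over the field soil pairs and 1 over the 7 soils. This filter removed a347_940, which was well above background on 18 arrays, so that probe was not tested there. With slide as a fixed block the counts were 0 in L1, 1 in L2, 4 in L3, 0 in L4, 1 in L6, 1 in the average, 1 between L1 and L4 and 0 over the 7 soils. As a random block (correlation 0.026) slide changed no count. With only 6 arrays per fit there were 138 calls in L2, 0 in L4 and 45 in L6, and 2 in the plain 2-group fit, where fewer arrays or a mixed group set the spread. One value per sequence gave 10 over the pairs, and joint adjustment 0 over the pairs and between L1 and L4. Array weights ran from 0.26 to 5.77 and gave 19 in L2, 14 in L4, 21 in L5, 8 in L6, 0 between L1 and L4, 23217 over the pairs, 1770 over the 7 soils and 3552 over the 6 field soils. Apart from the calls that ended with slide as a block and the changes explained by construction, the cause was not tested.

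Replicate numbers did not pair the samples: deviations from the soil means of arrays with the same number correlated at -0.01 on average, and 7 of 21 arrays correlated best with an array of their own number. With the replicate number as a block the field soil pairs gave 15 calls, and no other count moved by over 1.5 times.

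Leaving out 1 jar gave 2 (without L1 replicate 1, L2 replicate 2 or 3, L3 replicate 1 or 3, L5 replicate 1 or 3, L6 replicate 2, or LUFA replicate 1 or 2) to 10 (without L6 replicate 3) calls in the average, 1 to 2 in L1, 2 to 5 in L3, 0 to 3 in L4, 1 to 5 in L5, 1 to 3 in L6, 0 to 51 between L1 and L4, 0 to 51 over the pairs, 1 to 6 over the 7 soils and 0 to 1 over the 6 field soils. The 2 calls in L2 stood in all of its 6 fits. The zero in L4 came without L4 replicate 1 or any LUFA jar, and the 1 in the 6 field soils without L2 replicate 2. The mean correlation between soils was 0.52 with quantile normalization, against a simulated 0.48. With probes above background on all arrays it was 0.50 against 0.48, and the excess of the mean covariance over the simulation went from 0.0149 to -0.0005. The gene list alternatives were not run, since no list had a member.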

Other observations

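The tests of slide, stray spots and cysteine content below, and the choice of the most variable probes, were made after the results were seen. Some probes differed widely between jars of 1 soil. Among the 100 probes that varied most within soils (SD 3.22 to 4.71 on the log2 scale, against a median of 0.38 for all tested probes), 36 formed one co-varying group with a mean pairwise correlation of 0.93. The mean level of this group ran from -6.84 in L3 replicate 1 to 2.97 in L4 replicate 1, and in some soils the jars lay far apart: 2.83, 1.59 and -6.37 in L1, -5.50, 1.40 and -1.0 in LUFA, and 2.97, -6.42 and -5.14 in L4. In others they lay close together, at 2.46, 1.66 and 1.83 in L5 and at 0.78, 0.87 and 0.42 in L6. Since the probes were chosen for their spread within soils, their relation to soil was not tested. Slide accounted for 38.9% of the variance of the group, where chance gives 30% (permutation p = 0.244).

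A part of the array carries sequence left from library preparation. A 12-base stretch of a sequencing adapter, AGATCGGAAGAG, lies in 2281 of the 74528 probes and a stretch of a cDNA primer, CTCTGCGTTGAT, in 454, where 0.218 would carry either by chance. Of the 2795 probes with any such stretch 90.0% were tested, as were 90.1% of the others, at a median level of -2.92 against -2.44. One of the L4 probes named above, a81689_51, carries the adapter.

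For the large differences between jars, spot noise is argued against by the 2 spots of a probe, whose deviations from the soil means had a median correlation of 0.95 over the 12174 probes that differed more than 4-fold between jars of at least 1 soil. These probes were picked on the mean of the same 2 spots, which raises this correlation by an amount that was not tested. Over all tested probes the 2 spots differed by a median of 0.13 on the log2 scale. Slide as the whole cause is argued against because 49.1% of the variation within soils was left with slide in the model, where chance leaves 57.1%, although slide accounted for more variance than chance. Array brightness as the whole cause left 89.7%, where chance leaves 92.9%, even though component 2 followed the 75th percentile over the 21 arrays (Pearson -0.65, permutation p = 0.00191, 0.00382 after Benjamini-Hochberg over 2 components; Spearman -0.63, permutation p = 0.00275; Pearson -0.64 without the 2 farthest arrays). A difference in the state of the animals between jars may remain, but the labels record nothing about single jars and no biological explanation was tested.

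The 2 probes high in every field soil exceeded the LUFA array of the same slide. The smallest difference was 4.21 for a9999999_1 and, as a bound, 1.88 for a347_940, though L4 was on none of these slides. Both probes were picked on these same arrays, with all 18 field soil arrays above every LUFA array. Differences within a slide therefore had to be rises, so they are no separate test of slide. For a9999999_1 a stray spot is argued against by a gap of at least 3.74 between the lowest field soil array and the highest LUFA array at both spots. For a347_940 it is argued against as well, since at each spot all 18 field soil arrays and none of the LUFA arrays were well above background, with bounds on this gap of 1.40 and 0.91 and on the mean difference of 2.83 and 2.36 (SD within soils 0.74 and 0.73). For a9999999_1, the smallest difference in a soil over the other 3 scalings was 4.38, which argues against the background step or the scaling. For a347_940 the smallest bound was 0.63, with normexp, so the effect of the background treatment on its rise stays open. Pollution and other properties that set LUFA apart from the field soils were not separated by the design, and both stay open.

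A hypothesis that came from reading the sequence of a347_940 is that these probes read transcripts of cysteine-rich proteins. The reverse complement of a347_940 has a reading frame without a stop, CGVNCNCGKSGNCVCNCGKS, with 6 cysteines in 20 residues, and 0.0908% of tested probes have as many in any of the 6 frames, which describes the sequence that raised the hypothesis and does not test it. For a9999999_1 the most was 2, which 27.3% of tested probes reach, so the hypothesis finds no base in that sequence. The strand of the transcripts is not given, and a probe shows only 60 bases of each.

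Relabelling the arrays tested whether the counts exceeded chance. Each set of 100 labellings included the real one. Over the 7 soils, 7 of 100 labellings of the 21 arrays gave at least the real 2 calls, with 430 as the highest other. For the average against LUFA, 5 of 100 gave at least the real 6, with 14893 as the highest. Chance was therefore not excluded for these 2 counts. The real 0 over the 6 field soils is reached by any of the 100 labellings, so this count could not be tested, and the highest gave 2457. Why some relabellings gave so many more calls than the real labels was not tested. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In L1 (2 calls), L2 (2), L4 (3), L5 (3) and L6 (2) the real split alone, 1 of 10, reached its count, and the highest other gave 0. In L3 (2 calls) 2 of 10 did, and the highest other gave 26.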
